A study of Rattus norvegicus with 6 samples.

How the data were processed

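Poly-A RNA from the retinas of 6 male rats was made into libraries with a kit for which the labels name no strand marking, and was sequenced as read pairs, per the labels' protocols. Reads were aligned with HISAT2 2.0.5, per the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of FPKM for the whole series, with gene length, coordinates and biotype, per the file headers. It held 34170 genes, of which 10752 were at 0 in every library and 1287 had no symbol. The table's own symbols and coordinates were used.

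In each library the FPKM multiplied by the gene length was a whole multiple of 1 step, and 100% of the values came out within 0.05 of a whole number of fragments. The rebuilt fragments summed to between 12417686 and 19115426 per library. The denominators implied by the steps were between 0.974 and 1.04 times these sums, and what the authors divided by is not given in the sources used here. Floors cover counting error only, and the interval of a log2 difference covers the spread between animals.

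Libraries were grouped by the treatment in their labels. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with the group as the only term, eBayes with an intensity trend, a moderated two-sided test, Benjamini-Hochberg adjustment and a threshold of 0.05. FPKM were used as deposited, with no further scaling. The 46 gene lists were fixed before the data were examined, and the 44 with at least 3 tested genes, without the check of the labelled sex, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. For each list the p-values were also adjusted over the list alone. Where a symbol of a list occurred more than once, the entry with the highest mean was used. Body weight was compared with an exact permutation test.

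Named genes followed a rule fixed beforehand. It takes passing genes first and then, where fewer than 10 passed in a direction, genes with a symbol, a mean of at least 1 FPKM in the higher group, no overlap between groups and the smallest unadjusted p, up to 10 per direction. From each list discussed it takes the members that passed and up to 4 in all of smallest p, and it always takes a fixed set with Gfap, Vegfa, Mettl3, Mettl14, Wtap, Fto, Alkbh5 and Ythdf2. Some genes that the rule takes are not reported here. Other genes named in the text (Atf4, Hspa5, Ndufa1, Cryaa, Krt12, Nudt6, Tnf, Il6 and genes named only in the closing section) were chosen after their values were seen. The synthetases tested in the closing section were put into their groups before their values were looked at, and only the choice of which to name came afterwards. Of 95 genes that were named by the rule or passed over a list, 17 overlap another gene with a mean of at least 1 FPKM, and such genes can share reads.

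Alternatives were other pseudocounts, filters and scalings, other limma settings, voom on the rebuilt fragments, protein-coding genes alone, a replicate term, and leaving out each library. Added after the data were seen were the removal of a gene length trend per library by lowess, thinning of the fragments to 1 total, and leaving out genes that varied over 8-fold within a group. No 2 libraries agreed within sampling noise (chi-square per degree of freedom of at least 10.8). The functions were tested on simulated data for diabetic against control with 16182 genes tested, of which 200 changed by 1.5-fold or more. The genes of 1 further list were given a smaller shift and are not among the 200. There limma recovered 23.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold. Of the 133 genes called, 10 were unchanged. Noise was drawn separately for each gene, without a length trend, and the 200 changed genes had a mean of at least 1 FPKM. These shares are therefore not the recovery in the real data, where Smarcd1 at a log2 difference of -1.00 did not pass. Figures were drawn with matplotlib 3.10.9. The m6A peaks that the series describes were not analysed here.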

Results

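Retinas of 6 male Sprague-Dawley rats, an outbred laboratory stock, were profiled by poly-A RNA sequencing. In the diabetic group, 3 rats had received streptozotocin, a toxin that destroys the insulin-producing beta cells of the pancreas, and the 3 control rats had received the citrate vehicle. The toxin was given at 60 mg/kg on 5 days after a fast of 12 h, and rats above 16.7 mmol/L blood glucose 1 week later counted as diabetic. When the retinas were collected is not given in the sources used here. The series describes its aim as a survey of messenger RNA and of m6A, the methylation of adenosine in RNA, and the values analysed here are the gene expression values. The table gave FPKM, fragments scaled to gene length and library size, for 34170 genes. The fragments behind these values could be rebuilt and amounted to 16941864, 12417686 and 13035314 in control 1, 2 and 3 and to 18330641, 16277864 and 19115426 in diabetic 1, 2 and 3. A value of 3 fragments in a gene of 1 kb corresponded to between 0.158 and 0.248 FPKM, so genes of low expression were measured less precisely, most of all in control 2 and control 3. Each library comes from a separately weighed animal, and the p-values of single genes and of body weight rest on the spread between these animals. The camera p-values compare the genes of a list with other genes at a preset correlation, so they are not a measure of that spread. The labelled body weight was 106.6 ± 3.59 g (SD, n = 3) in the control rats and 102.3 ± 1.81 g (SD, n = 3) in the diabetic rats, a difference of -4.33 g (p = 0.2, exact permutation test, two-sided). With 3 rats per group this test cannot give a p below 0.1, so it leaves open whether the weights differed.

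The comparison asks which messenger RNAs differ between the diabetic and the control retina. Among the genes of smallest unadjusted p, Asns, the asparagine synthetase, measured 16.6 ± 1.27 FPKM in control and 45.4 ± 9.09 FPKM in diabetic retina (SD, n = 3 each), a log2 difference of 1.41 with a standard error of 0.15. The neutral amino acid transporters Slc1a4 and Slc38a2 had log2 differences of 1.42 and 0.86, the stress-induced regulator of growth signalling Sesn2 had 1.26, the glutathione-degrading enzyme Chac1 had 1.22 and the mitochondrial folate enzyme Mthfd2 had 1.76. Smarcd1, a subunit of SWI/SNF chromatin remodelling complexes, was at 294.2 ± 28.3 FPKM in control and 146.3 ± 2.89 FPKM in diabetic retina, with a 95% interval of the log2 difference from -1.21 to -0.79. For the dopamine receptor gene Drd4, which is expressed in photoreceptors, the means were 92.7 ± 13.4 and 49.6 ± 2.43 FPKM. None of these genes passed the threshold over all genes, so their values are differences that did not pass.

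Over all 16363 genes tested with limma on log2(FPKM + 0.5), 0 genes passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.127. At an unadjusted p below 0.05 there were 3255 genes, of which 1498 were higher and 1757 lower in diabetic retina, where 818 were expected by chance. The groups did not overlap in 4289 genes, or 26.2%, where chance gives 10%. The count of 0 became 2 with voom on the rebuilt fragments, which called Smarcd1 and Asns with adjusted p of 0.0299 and 0.0473. It was 1 without control 2, 4 without diabetic 1 and 1 without diabetic 2, and Asns and Smarcd1 were not among the genes called there. The count at an unadjusted p below 0.05 was 2066 without diabetic 2. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Rescaling to TPM moved the median log2 difference of all genes by 0.13 and changed the split of the genes at an unadjusted p below 0.05 to 3009 higher and 692 lower.

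The other genes with the smallest unadjusted p, chosen by a rule fixed before the data were examined, had log2 differences between 0.75 and 1.46 in the higher direction. They were the transcription factor gene Cebpb (0.97), Spata6 (0.75), the clone-named gene AABR07028970.2 (1.20) and Meikin (1.46, with a control mean of 0.27 FPKM, close to the value of 3 fragments). In the lower direction they were Cyth2 (-0.64), which encodes a guanine nucleotide exchange factor, Dynll1 (-0.57), a dynein light chain gene, Alpl (-0.65), the tissue-nonspecific alkaline phosphatase gene, Coq6 (-0.63), an enzyme of coenzyme Q synthesis, the transcription factor gene Etv4 (-0.92), Nme3 (-0.68), LOC100910678 (-0.84) and LOC100363469 (-0.77). All of them shared the adjusted p of 0.127 in limma. The files place Smarcd1 (ENSRNOG00000061572) on chromosome 7 from 141355994 to 141366732 on the plus strand, and Asns (ENSRNOG00000007546) on chromosome 4 from 33743364 to 33761163 on the minus strand, in a genome build that is not given in the sources used here.

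**Figure D1:**
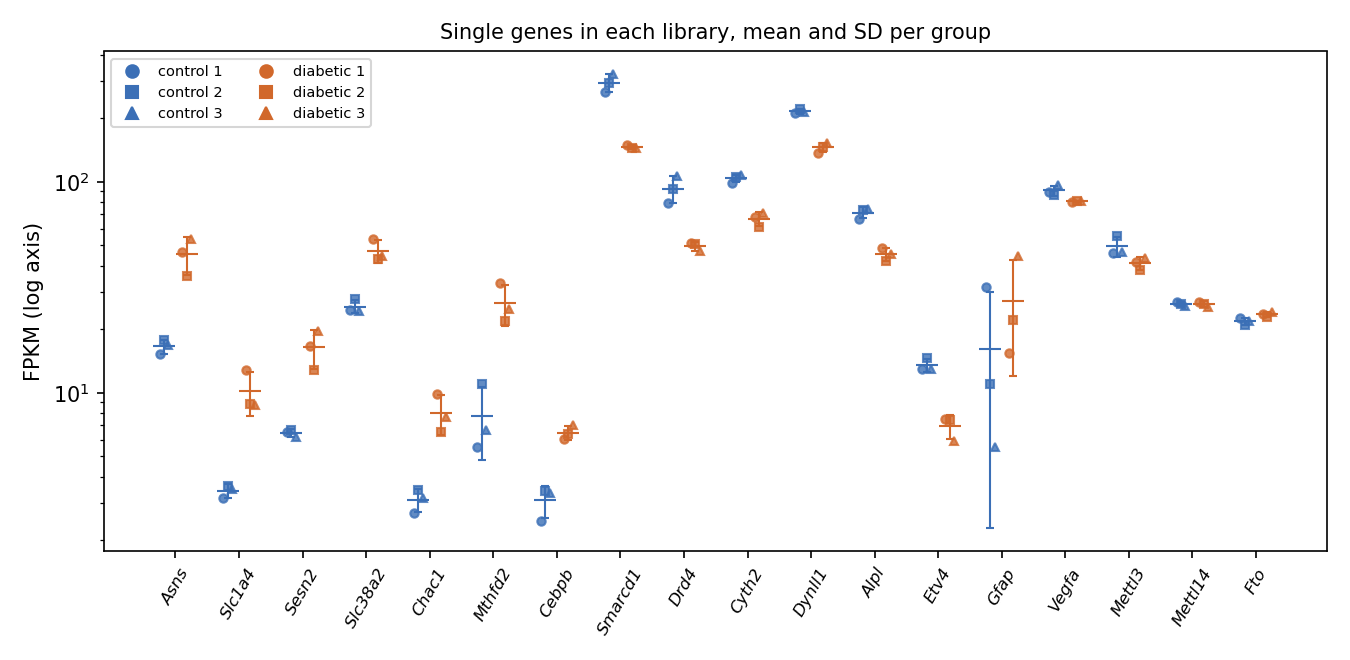
FPKM on a log axis for 18 single genes in each of the 6 libraries, with control in blue and diabetic in orange, marker shapes for the replicate numbers, and horizontal ticks and bars for the mean and SD of 3 libraries. The diabetic values of Asns lie above all control values and those of Smarcd1 below them, while Gfap overlaps between the groups and Mettl14 has means of 26.3 FPKM in both.

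In the list of the unfolded protein and integrated stress response, 8 of 20 tested genes passed when adjusted over the list alone, and 0 passed over all genes tested. Asns, Sesn2, Chac1, Trib3 (log2 difference 0.89), Atf3 (1.12) and Herpud1 (0.57) rose, and the phosphatase subunit gene Ppp1r15a (-0.52) and the secreted factor gene Manf (-0.35) fell. Messenger RNA of the transcription factor Atf4 was at 467.2 ± 54.3 FPKM in control and 429.5 ± 37.1 FPKM in diabetic retina, and that of the endoplasmic reticulum chaperone Hspa5 was at 124.5 ± 6.25 and 128.1 ± 13.2 FPKM, and neither passed. As a whole this list was not shifted against other genes (adjusted p = 0.472 by camera), and its median of -0.02 and its mean of 0.24 differed in sign.

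Most genes of the mitochondrial respiratory chain were lower in diabetic retina, and so were other short, abundant genes. Of the 49 nuclear-encoded genes tested, 48 had a negative log2 difference and 32 fell when adjusted over the list alone, with 0 past the threshold over all genes tested. The ATP synthase subunit gene Atp5mc1 went from 118.0 ± 6.53 to 82.2 ± 5.74 FPKM, the cytochrome c1 gene Cyc1 from 111.7 ± 6.27 to 87.0 ± 3.36 FPKM, and the complex I subunit gene Ndufb10 from 80.0 ± 5.70 to 60.9 ± 2.80 FPKM. The exception was Ndufa1, which was at 65.4 FPKM in diabetic 1 and between 0.554 and 1.46 FPKM in the other libraries. The list had a median log2 difference of -0.34 and passed the camera test against other genes (adjusted p = 2.41e-14), but not with an estimated correlation (adjusted p = 0.92 with an estimated correlation). Random lists matched on gene length and mean expression had a median of -0.27. The median of the respiratory chain list was -0.20 with TPM, where that of all genes was 0.13, and -0.17 under quantile normalization. The 13 genes encoded by the mitochondrial genome had a median of 0.07 and did not pass (adjusted p = 0.863 by camera). Their median was 0.20 with TPM, 0.18 with the length trend removed and 0.22 under quantile normalization, where the list passed (adjusted p = 0.0148, in a range from 0.0148 to 0.979 over all alternatives).

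Cytosolic ribosomal protein genes were also lower, with 64 of 66 below control, a median log2 difference of -0.37 and a camera adjusted p of 9.08e-14 (adjusted p = 0.92 with an estimated correlation). Random lists matched on gene length and mean expression had a median of -0.28. The median of the ribosomal protein list was -0.24 with TPM, where that of all genes was 0.13, and -0.17 under quantile normalization. When adjusted over the list alone, 5 fell, among them Rpl13a, Rps2, Rps23 and Rps21, and 0 passed over all genes. Many ribosomal protein genes have near-identical copies in the genome, and how the counting divided reads between copies is not given in the sources used here, so single values in this family are uncertain. In the glycolysis list, 17 of 21 genes were lower, and Pgam1 (log2 difference -0.43), Eno1 (-0.44) and Aldoa (-0.37) fell when adjusted over the list alone, with 0 past the threshold over all genes. Its camera adjusted p was 0.00382 (adjusted p = 0.92 with an estimated correlation), and without control 1 it was 0.0519, in a range from 8.52e-04 to 0.0519 when 1 library was left out. Its median of -0.14 was -0.01 with TPM (adjusted p = 0.0137 by camera). It was -0.06 under quantile normalization, where the adjusted p was 0.630, in a range from 8.52e-04 to 0.92 over all alternatives. Among heat shock protein genes 11 of 13 were lower, and Hspe1 (-0.56) and Hspa8 (-0.40) fell when adjusted over the list alone, with 0 over all genes. The camera adjusted p of that list was 0.0118 (adjusted p = 0.92 with an estimated correlation). Its median of -0.32 was -0.18 with TPM (adjusted p = 0.00331 by camera). It was -0.18 under quantile normalization, where the adjusted p was 0.0796, in a range from 0.00320 to 0.92 over all alternatives.

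Genes of rod phototransduction, the light response of the rod photoreceptors, were lower in 19 of 25 cases. The cyclic nucleotide-gated channel subunit gene Cngb1 fell from 203.7 ± 10.5 to 161.1 ± 4.57 FPKM and the recoverin gene Rcvrn fell from 2372 ± 166 to 1639 ± 102 FPKM when adjusted over the list alone, with 0 past the threshold over all genes. Rom1 and Gnat1 had log2 differences of -0.52 each that did not pass. The list had a camera adjusted p of 0.00138 (adjusted p = 0.92 with an estimated correlation). Its median of -0.19 was -0.05 with TPM, where the median of all genes was 0.13 and the list still passed (adjusted p = 0.00130 by camera). Under quantile normalization the median of the list was 0.04 and the adjusted p was 0.946, in a range from 1.18e-04 to 0.946 over all alternatives. In the cone list the members moved apart when adjusted over the list alone, where Opn1sw (log2 difference 0.81) and Slc24a2 (0.48) rose and Pde6h (-0.38) and Gngt2 (-0.49) fell, with 0 past the threshold over all genes. The cone list as a whole did not pass (adjusted p = 0.863 by camera).

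Genes of insulin and insulin-like growth factor signalling were higher in diabetic retina in 18 of 20 cases. When adjusted over the list alone, 9 rose, and 0 passed over all genes. The receptor gene Igf1r went from 7.40 ± 1.65 to 12.6 ± 0.54 FPKM, the insulin receptor gene Insr from 9.39 ± 1.33 to 13.4 ± 0.80 FPKM and the kinase gene Pdpk1 from 12.2 ± 2.40 to 18.6 ± 2.10 FPKM. Grb10, Pik3ca, Igfbp2, Foxo3 and Gsk3b were also among them. The median log2 difference was 0.28 and the camera adjusted p was 2.56e-04 (adjusted p = 0.92 with an estimated correlation). The median was 0.42 with TPM, where that of all genes was 0.13. It was 0.23 under quantile normalization and 0.15 with the length trend removed.

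The list of reactive gliosis and retinal stress, the response of glial cells to injury, was higher in 15 of 18 genes. The medians of the list overlapped between the groups, with 0.44, -0.16 and -0.29 in control 1, 2 and 3 and 0.19, 0.47 and 1.02 in diabetic 1, 2 and 3, against the control mean. Control 1 was also the highest control library in the microglia (0.36), interferon response (0.36) and complement (0.45) lists. The median log2 difference of the gliosis list was 0.56 and its camera adjusted p was 0.00372 (adjusted p = 0.92 with an estimated correlation). The call was lost without control 3 (adjusted p = 0.109) and without diabetic 3 (adjusted p = 0.086), in a range from 2.90e-07 to 0.109 when 1 library was left out. Cebpb rose when adjusted over the list alone, and 0 genes passed over all genes tested. Gfap, the intermediate filament gene of reactive glia, was at 31.8, 11.05 and 5.52 FPKM in control 1, 2 and 3 and at 15.4, 22.1 and 44.5 FPKM in diabetic 1, 2 and 3, so the groups overlapped (adjusted p = 0.438, limma). Fgf2 went from 3.27 ± 1.38 to 8.34 ± 2.54 FPKM and passed when adjusted over the list of neurotrophic factors alone, but not over the gliosis list. It overlaps the gene Nudt6 on the opposite strand, at 16.9 FPKM, and reads from such partners cannot be told apart without strand. Tnf and Il6 were listed at 0 in all 6 libraries. The list of microglia and macrophage genes had 10 of 15 genes lower and did not pass (adjusted p = 0.330 by camera), while without control 2 it did (adjusted p = 0.0272, in a range from 0.0272 to 0.811 when 1 library was left out). The complement list did not pass (adjusted p = 0.383), while without control 1 it did in the higher direction (adjusted p = 0.00859, in a range from 0.00859 to 0.834 when 1 library was left out). The interferon response list did not pass (adjusted p = 0.665).

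**Figure D2:**
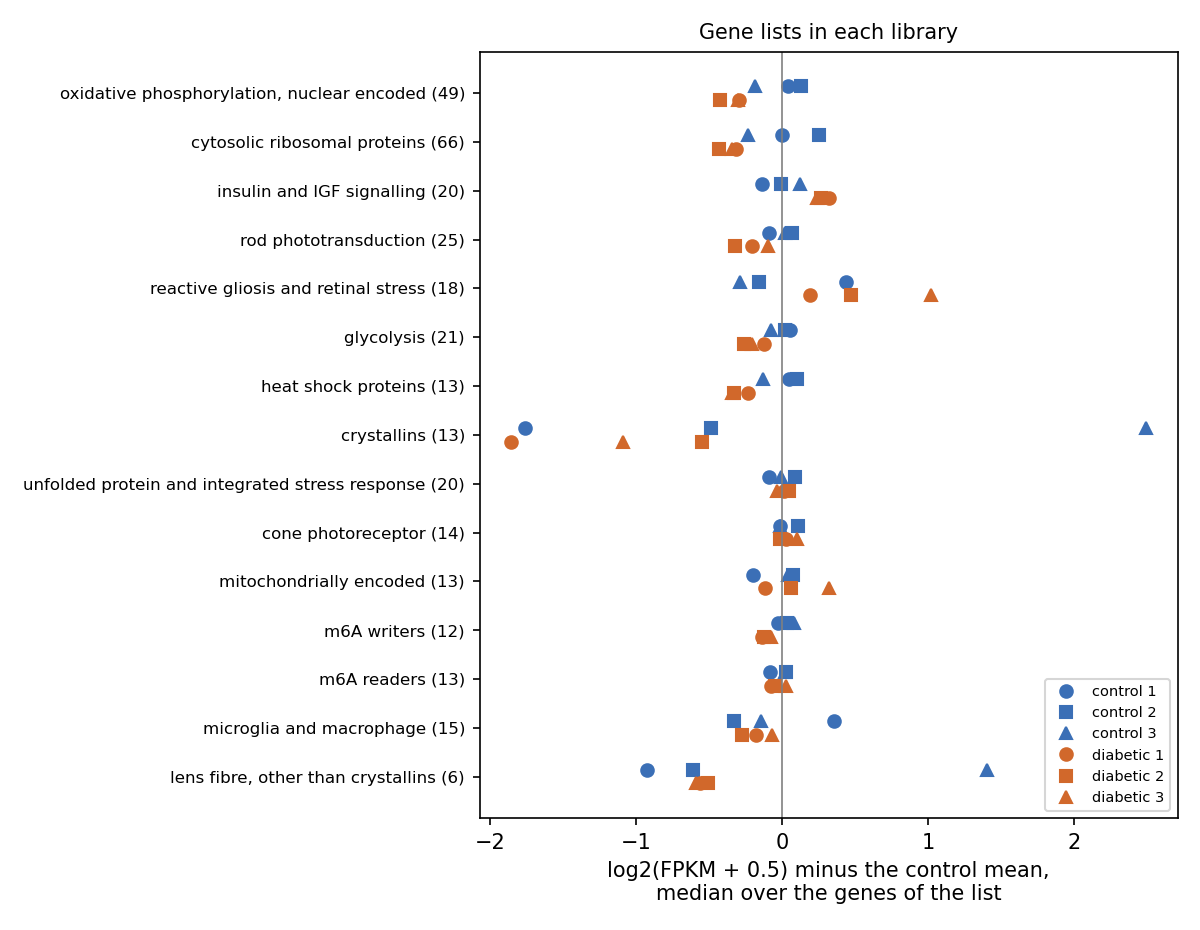
Median over the tested genes of each list of log2(FPKM + 0.5) minus the control mean of the gene, on the x axis, for 15 lists with their numbers of tested genes, with 1 point per library, control in blue and diabetic in orange. In the respiratory chain list the diabetic libraries lie at -0.30, -0.42 and -0.30 against 0.04, 0.13 and -0.19 in control, and in the crystallin list control 3 stands apart at 2.49.

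Among the genes that write, remove and read m6A, 0 passed, over all genes and when adjusted over each list alone. The catalytic subunit gene Mettl3 was at 49.4 ± 5.41 FPKM in control and 41.2 ± 2.80 FPKM in diabetic retina (log2 difference -0.26, adjusted p = 0.223, limma), and its partner Mettl14 was at 26.3 ± 0.55 and 26.3 ± 0.82 FPKM. Wtap had a log2 difference of -0.13, the demethylase genes Fto and Alkbh5 had 0.11 and 0.05, and the reader gene Ythdf2 had -0.06. Virma, a scaffold subunit, had 0.33 and the reader gene Hnrnpc had -1.06, without passing. The camera adjusted p values of the 3 lists were 0.472 for writers, 0.665 for erasers and 0.863 for readers. With fry for mixed directions, which asks whether members changed in either direction, writers (adjusted p = 0.0283) and readers (adjusted p = 0.0323) passed. Erasers did not (adjusted p = 0.908), and 19 of the 44 lists tested passed with that setting. Vegfa, the vascular growth factor gene, was at 90.9 ± 4.89 and 80.7 ± 0.50 FPKM (adjusted p = 0.239, limma).

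Signs of tissue carried along in the dissection differed between libraries. The crystallin genes, which encode the main proteins of the lens, had a camera adjusted p of 0.0147 in the lower direction (adjusted p = 0.92 with an estimated correlation), with 0 of 13 genes passing when adjusted over the list alone. Cryaa was at 130.4 FPKM in control 3 and between 2.51 and 17.8 FPKM in the other 5 libraries. Without control 3 the adjusted p of the list was 0.683, and without diabetic 1 it was 0.129, in a range from 1.03e-05 to 0.683 when 1 library was left out. The corneal keratin gene Krt12 was at 6.58 FPKM in control 2 and 6.52 FPKM in diabetic 1 and between 0.289 and 1.61 FPKM in the others. The median of the retinal pigment epithelium list was at -0.50 and -0.49 in diabetic 2 and 3 and at 0.14 in diabetic 1, against 0.21, 0.17 and -0.12 in control 1, 2 and 3. That list did not pass (adjusted p = 0.314 by camera), while without diabetic 1 it did in the lower direction (adjusted p = 0.00547, in a range from 0.00547 to 0.888 when 1 library was left out). Of the remaining lists, Ier2 among the immediate early genes and Mvd among the cholesterol synthesis genes fell, and Optc among the genes of cornea, iris and ciliary body rose, when adjusted over the list alone, with 0 past the threshold over all genes. In all, 8 of 44 lists tested passed by camera, 2 higher and 6 lower, and 0 passed with an estimated correlation. Other divisions of the 6 libraries into 3 and 3 passed up to 12 lists.

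Values also followed the length of the gene. In 1637 tested genes of 421 to 953 nt the median log2 difference was -0.15, and in 1637 genes of 5083 nt or more it was 0.17. Control 3 had -0.10 and 0.11 in these genes, against the control mean. The median gene length was 785 nt in the respiratory chain list and 633 nt in the ribosomal protein list, against 3490.5 nt in the insulin list. When the length trend of each library was removed, the medians of these lists were -0.21, -0.25 and 0.15, and the camera adjusted p values were 2.84e-10, 7.54e-10 and 0.00321 at the preset correlation. Without that removal, all 3 calls were lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation).

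**Figure D3:**
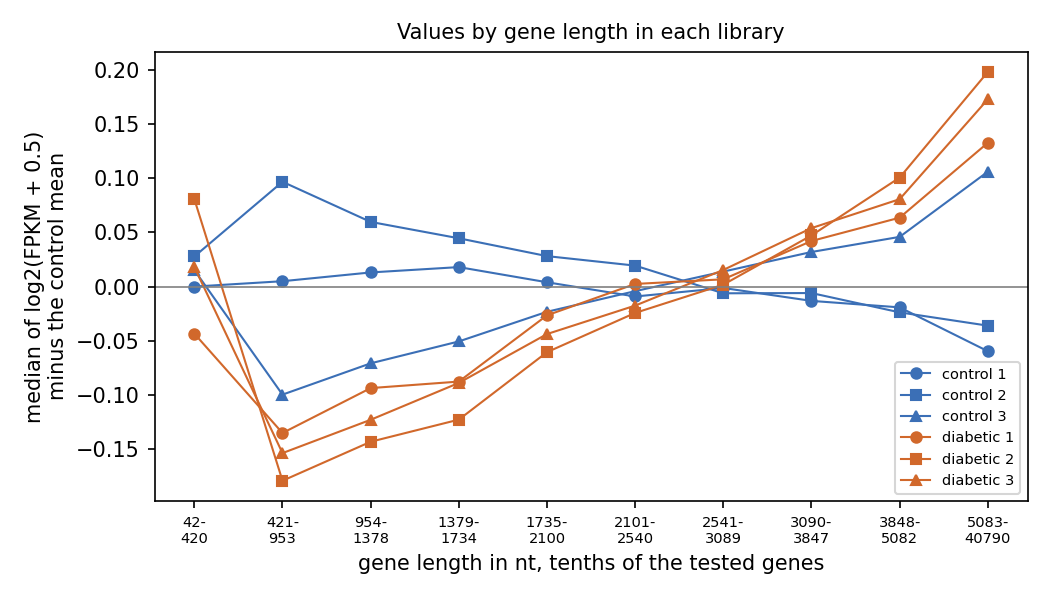
Median over genes of log2(FPKM + 0.5) minus the control mean of the gene, on the y axis, for 10 groups of the 16363 tested genes by gene length in nt, with 1 line per library. Apart from the group of shortest genes, the 3 diabetic libraries run from below 0 in short genes to above 0 in long genes, and control 3 runs the same way, with 0.11 in the longest genes.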

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

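The gene length, thinning and 8-fold settings were chosen after the data were seen, and the rest were planned. The count of 0 genes (limma, 3255 at an unadjusted p below 0.05) held in 19 of 24 alternatives. It was 2 with voom on the rebuilt fragments and 1 with fragments thinned to 1 total, and from 0 to 4 when 1 library was left out: 1 without control 2, 4 without diabetic 1 and 1 without diabetic 2. Asns and Smarcd1 were called with voom only. The cause of these changes in the count was not tested. At an unadjusted p below 0.05 the count was from 2066 (without diabetic 2) to 4015 (without control 3) when 1 library was left out. Tests of the edgeR and DESeq2 kind were not run. TPM moved the median of all genes by 0.13 and thinning, where the sum of fragments was the denominator, by 0.05, so signs of small differences depend on the scaling.

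Libraries with the same replicate number showed no shared deviation, with correlations of -0.05, -0.08 and 0.00. Whether the numbers pair the animals cannot be told from these values. With the replicate block 0 genes passed (smallest adjusted p 0.227), 2790 had an unadjusted p below 0.05 and 8 lists passed.

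The count of 8 lists was 0 with an estimated inter-gene correlation, 0 with fry in 1 direction and 19 with fry for mixed directions, and between 6 and 11 when 1 library was left out. With an estimated correlation the adjusted p of all 8 lists was 0.92. The estimates for these lists ran from 0.186 for heat shock to 0.810 for crystallins, against the preset 0.01. They were 0.635 for the respiratory chain and 0.561 for ribosomal proteins. The 8 calls thus rest on a preset correlation below the estimate for each list. Fry in 1 direction asks whether a list changed at all and not whether it differs from other genes. With it the adjusted p was 0.361 for the rod, insulin, glycolysis, respiratory chain, heat shock and ribosomal protein lists, 0.447 for gliosis and 0.703 for crystallins. The cause of the fry results was not tested. Under quantile normalization the adjusted p was 0.946 for rod phototransduction, 0.630 for glycolysis and 0.0796 for heat shock. When 1 library was left out, the adjusted p ran from 2.90e-07 to 0.109 for gliosis, lost without control 3 and without diabetic 3 (0.086), from 8.52e-04 to 0.0519 for glycolysis, lost without control 1, and from 1.03e-05 to 0.683 for crystallins, lost without control 3 and without diabetic 1 (0.129). The respiratory chain, ribosomal protein and insulin lists passed in 17 of 19 alternatives each, all but the estimated correlation and fry. Some lists passed only under alternatives. Of 18 alternatives, pericytes passed in 4 (without the filter 0.0403, TPM 0.0462, quantile normalization 0.0472, without control 2 0.0469) and cholesterol synthesis in 3 (without the filter 0.0276, without diabetic 1 8.52e-04, length trend removed 0.0122). Others passed in 1 alternative, such as immediate early genes without diabetic 3 (0.0146), endothelial cells without control 2 (0.0156) and ribbon synapse with quantile normalization (0.00247).

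Of 2923 pairs of a named gene and an alternative, 2907 kept their sign and their side of the threshold, and 2 passed (Asns and Smarcd1 with voom). The sign turned for 6 genes that never passed: Mettl14 with TPM (0.133), median-ratio factors (0.00435), quantile normalization (0.0337), voom (0.00382) and thinning (0.0521), Wtap with TPM (0.00169), Ythdf2 with TPM (0.0792) and Alkbh5 with the length trend removed (-0.0512). When 1 library was left out, Mettl14 ran from -0.0241 to 0.0201, Alkbh5 from -0.0643 to 0.117, Alkbh3 from -0.0181 to 0.0968 and Aldh1a1 from -0.437 to 0.0352. Body weight differed by between -5.95 and -2.40 g when 1 animal was left out. The depth limits low genes most, and 1.5-fold changes were recovered in 23.9% of simulated cases, with noise drawn separately for each gene.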

Other observations

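The test of lens carry-over was chosen only after the result was seen. The amino acid hypothesis was formed after 6 genes and 4 synthetases had been seen, and its test on 16 other synthetases was fixed before their values were looked at. The other tests named here were fixed before their results were seen, although the length trend itself had been seen. For matched random lists this holds for the respiratory chain, ribosomal protein and insulin lists. No prediction was written for the rod, glycolysis, gliosis and heat shock lists.

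The enzymes that charge transfer RNA with amino acids did not all differ in 1 direction. The groups below were divided from general knowledge, without a source list, after 4 of these enzymes had been seen. Among cytosolic synthetases, the 4 already seen among the smallest p values, Tars, Cars, Mars and Aars, had a mean log2 difference of 0.70. Another 8 that are counted among the targets of the transcription factor ATF4, and whose values had not been looked at, were all higher in diabetic retina, from 0.07 for Wars to 0.68 for Iars, which went from 13.7 ± 1.58 to 22.3 ± 2.85 FPKM (SD, n = 3). The remaining 8 cytosolic synthetases were all lower, from -0.29 for Farsa to -0.01 for Qars. The 16 mitochondrial synthetases had a mean of 0.02 and went both ways. All 5 further amino acid transporters tested were higher, with a mean of 0.20, but the groups overlapped in all of them except Slc7a5. Of 7 enzymes of serine, proline and one-carbon metabolism, 5 were higher, led by Pycr1 at 0.98, while Phgdh and Psat1 were at -0.13 and -0.21. None of these genes passed over all genes tested (limma).

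A hypothesis for the higher values of Asns, Sesn2, Chac1, Slc1a4, Slc38a2 and Mthfd2 is an amino acid response of the ATF4 type. It predicted that the 8 unseen ATF4-target synthetases would exceed the other 8, and they did, with means of 0.36 and -0.10 (p = 7.77e-05, exact permutation test, one-sided, the smallest p that 12870 arrangements can give). Genes are not independent replicates, so this p describes this division of the genes in these 6 libraries and depends on it. The gene length trend is argued against by its size, with median log2 differences between -0.15 and 0.17 over the length groups. Its removal could change little from the outset, and the median of the 6 genes was 1.33 before and 1.32 after it. Whether diabetes, food intake or another difference between the groups lies behind the pattern was not tested. Ppp1r15a, a known target of this branch, fell when adjusted over its list alone (log2 difference -0.52), and Atf4 messenger RNA itself, Phgdh and Psat1 were not higher, which a response of all ATF4 targets through more Atf4 messenger RNA would not give, and ATF4 protein was not measured.

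The lower respiratory chain and ribosomal protein lists are made of short, abundant genes, and the higher insulin list of long ones. Among 10000 random lists matched on gene length, the medians of the respiratory chain and ribosomal protein lists were at percentile 0.01 each, the smallest these lists can give, and the insulin list at 99.96. Matched on mean expression they were at 0.01, 0.01 and 100. Matched on both, they were at 1.91, 0.16 and 99.96. The random genes were drawn separately, while the estimated correlations within these lists were 0.635, 0.561 and 0.337. Correlated genes can leave such a range more easily, so the percentiles do not decide whether these trends are the whole cause. Matched random lists had medians of -0.27 and -0.28 against -0.34 and -0.37 observed in the respiratory chain and ribosomal protein lists. Most of the size of both decreases was thus shared by other short, abundant genes, which could include genes of the other of these lists. A difference in RNA quality or library preparation between the groups, or diabetes, may lie behind that shared part, and the design does not separate them. For rod phototransduction and glycolysis the medians lay within the range matched on both, at percentiles 20.31 and 16.76, and for gliosis and heat shock outside it, at 100 and 0.04.

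The lower crystallin list is in line with lens tissue carried over in control 3. Without that library the adjusted p of the list was 0.683, and the lens fibre genes outside the crystallins also stood highest there, with Lim2 at 5.08 FPKM against 0.319 or less in the other libraries and Mip at 2.75 FPKM against 0.1802 or less.

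The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. At an unadjusted p below 0.05 the real division gave 3255 genes and the highest other 1751, and 1 of 10 divisions reached the real count. At an adjusted p below 0.05 the real division gave 0 genes and the highest other 2. All 10 of 10 gave at least as many, which a real count of 0 makes certain, so this comparison decides nothing. For gene lists the real division gave 8 and the highest other 12, and 5 of 10 gave as many, so a count of 8 lists by camera does not set the real groups apart. The division of control 1, control 2 and diabetic 1 from the rest gave both the 1751 genes and 12 lists, and that of control 1, diabetic 1 and diabetic 2 from the rest also gave 12 lists.

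Among 10084 genes with a mean of at least 5 FPKM, 50 varied over 8-fold within a group, Ndufa1 among them.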
